A study of Mus musculus with 6 samples.

How the data were processed

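RNA-seq of 6 libraries of the mouse line AY-mICC was used, 3 of control cells (shCon) and 3 of cells with a Copa knockdown (shCopa). Per the labels' protocols, total RNA was isolated with TRIzol, and libraries made with a standard mRNA kit were sequenced as read pairs on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of estimated counts per Ensembl gene, with values given to 2 decimals; 10.6% to 11.9% of all values in a library were not whole. Per the submitters' processing notes, Trimmomatic, HISAT2 2.0.5, HTSeq, featureCounts and DESeq2 were used with the mouse build GRCm39. Which of these programs gave the estimated counts, the annotation release and the strand setting are not given in the sources used here. Reads shared by near-identical genes or by a gene and an antisense partner may therefore have been divided in ways the deposited counts do not show. An annotation of GRCm39 was not used here, so no coordinates are given.

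The table held 55414 gene identifiers. Symbols came from a name table of the GENCODE M21 annotation and were found for 52081; the other 3333 identifiers held 0.201% to 0.464% of the counts of a library and were kept under their identifiers. For 67 symbols carried by more than 1 identifier, the identifier with the higher mean count was used. All 6 columns matched a sample title. Estimated counts were rounded to whole numbers. Library totals ran from 19634938 to 24546204, so 3 counts, used as the floor for a gene with no counts, corresponded to 0.123 to 0.152 CPM in 1 library. This floor covers counting error only. The 10 most abundant genes took 4.83% to 5.27% of counts.

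Differences between shCopa and shCon were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter on low counts, robust quasi-likelihood fits and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over 14807 genes and a threshold of 0.05. A gene is said to rise, fall or change only where it passed that threshold. Log2 fold changes are shCopa minus shCon, with the SE taken from the fitted change and its F statistic. Fold changes and the percentage of the control level come from the fit, and CPM values use TMM-scaled library sizes, as mean ± SD over n = 3. The biological coefficient of variation was 0.165. Replicates were compared by Pearson's r across genes and by a chi-square of their counts; its value per degree of freedom was 4.393 to 8.018 for pairs within shCopa and for shCon 2 with shCon 3, and 77.9 and 89.71 for pairs with shCon 1, so no pair agreed within sampling noise.

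A set of 32 gene lists was fixed before the data were examined. Fixed with it were the tests of genes and of lists, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes, with an estimated correlation, and with fry. These p-values were adjusted over 30 lists. Lists share some members, so they are not independent. Beside the calls adjusted over all genes, counts adjusted over the list alone are given. Genes named in the text were all COPI coat subunits; the 8 largest rises and 8 largest falls among genes past the threshold with groups that did not overlap, at least 10 CPM in the higher group and a proper symbol; up to 3 members of each list with the smallest adjusted p; and, whatever their result, Cgas, Sting1, Ifnb1, Cxcl10, Ccl5, Cd274, H2-K1, H2-D1, B2m, Tap1, Nlrc5, Hspa5, Ddit3 and Calr. Some genes that meet this rule are not reported here.

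The edgeR steps were tested on simulated data, counts drawn for 14807 genes from the means, dispersions and library sizes of these samples. The filter kept 14523 of these genes. The genes to change were drawn from those with a mean over 1 CPM. Of genes changed 1.5-fold, 20.9% of 67 were recovered, of those changed 2-fold 86.6% of 67, and of those changed 4-fold 95.5% of 66, with 14 false calls among 149. Alternatives were other scaling factors, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds, each library left out in turn and, added after the data were seen, offsets that remove each library's trend on transcript length and GC content. Lengths, GC content and 3' UTR sequences came from GENCODE M21 transcripts matched by gene identifier, with a length for 99.8% of tested genes. A scan of 3' UTR hexamers covered 11475 genes with a 3' UTR of at least 50 bases and a log2 CPM over 1. Log2 fold changes beyond 3 in size were set to 3 with their sign kept. Hexamers were scored after fitted trends on 3' UTR length, transcript length, the GC content of both and expression were removed. The null came from 1000 shuffles of the fold changes that remained. The scan used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.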

Results

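RNA was profiled in AY-mICC, a mouse cell line from a study of intrahepatic cholangiocarcinoma, a cancer of the bile ducts within the liver. Per the labels, 3 libraries came from control cells (shCon) and 3 from cells with a Copa knockdown (shCopa), whose sample titles carry the usual prefix for a short hairpin RNA. Copa encodes the alpha subunit of COPI, the protein coat of vesicles that carry proteins back from the Golgi apparatus to the endoplasmic reticulum (ER). The total of estimated counts per library was 22282624, 23593108 and 24546204 in shCon replicates 1 to 3, and 21935312, 22824646 and 19634938 in shCopa replicates 1 to 3. On the log2 scale of counts scaled to library size (CPM) over tested genes, the shCopa libraries correlated with one another at r = 0.9888 to 0.9907 and shCon 2 with shCon 3 at 0.9898. shCon 1 stood apart from its group, at r = 0.9734 with shCon 2 and 0.9719 with shCon 3. The first principal component held 68.3% of the variance and parted the groups. The second held 17.1% and parted shCon 1 from shCon 2 and 3. No labels say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

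The comparison of shCopa with shCon asks which transcripts change in these tumour cells when Copa is lowered. The series title connects COPI to immunity carried by CD8+ T cells. Copa (ENSMUSG00000026553) was at 420, 517 and 527 CPM in the shCon libraries and at 186, 182 and 187 CPM in the shCopa libraries. Its mean fell from 488 ± 59.1 CPM to 185 ± 2.91 CPM (SD, n = 3 each), a log2 fold change of -1.40 ± 0.11 (SE), which left 37.9% of the control level (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000149). Among the other subunits, Copz2 fell (log2 fold change -1.70 ± 0.31) and so did Cope (-0.74 ± 0.19), while Copb1 (0.47 ± 0.09) and Arcn1 (0.38 ± 0.11) rose. The remaining 4 did not pass the test: Copg1 (0.22 ± 0.08), Copb2 (0.21 ± 0.10), Copz1 (0.10 ± 0.16) and Copg2 (-0.17 ± 0.09). Cope stood at 94.4 CPM in shCon 1 and at 60.3 and 56.3 CPM in shCon 2 and 3, and Copz2 at 14.7, 7.51 and 7.85 CPM. Without shCon 1, the log2 fold change of Cope was -0.48 and that of Copz1 was 0.30 (adjusted p = 0.000232). The call of Cope was lost without any 1 of the 3 shCopa libraries, that of Arcn1 without shCon 2 or any 1 of the shCopa libraries, and Copz1 turned to -0.01 without shCon 3. Of the 9 coat subunits, Copa included, 2 rose, 3 fell and 4 did not pass. Adjusted over the list alone, 3 of these subunits rose and 3 fell. Their median log2 fold change was 0.10 (0.01 without shCon 2, -0.01 without shCon 3 and 0.14 without shCon 1), their mean -0.29 and their camera direction down.

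**Figure D1:**
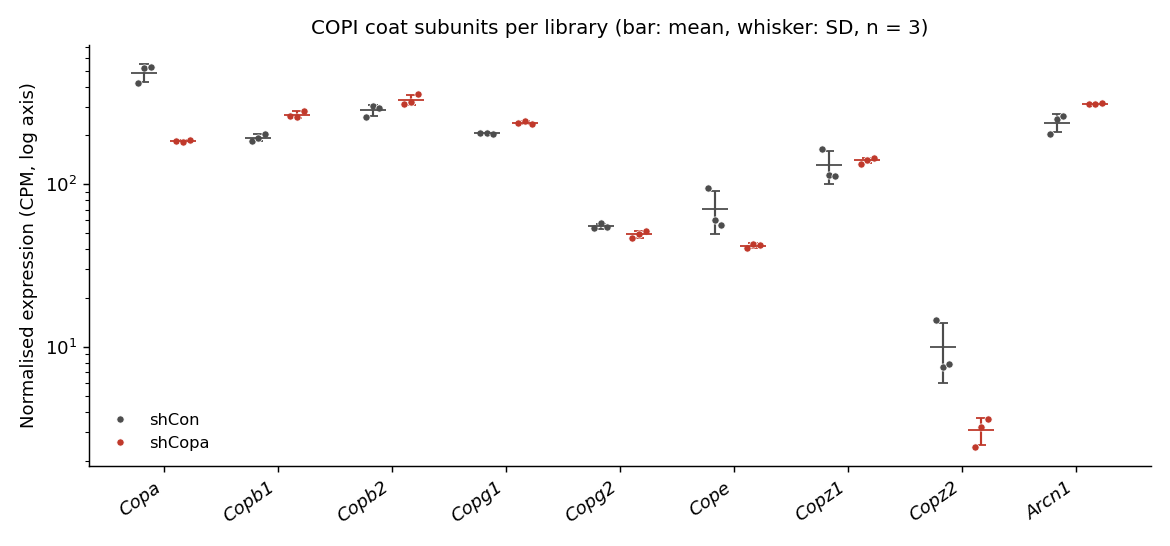
Normalised expression of the 9 COPI coat subunits (vertical log axis, CPM) in the 3 shCon libraries (grey points) and the 3 shCopa libraries (red points), with the mean as a bar and the SD as a whisker. Copa lies between 420 and 527 CPM in shCon and between 182 and 187 CPM in shCopa, while in shCon 1 (left grey point of each gene) Cope, Copz1 and Copz2 lie above the other shCon libraries.

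Of 14807 genes tested, 5411 differed, 2691 higher and 2720 lower in shCopa, and by at least 2-fold 1118 were higher and 935 lower. In 8002 genes (54%) the libraries of the groups did not overlap, against 10% by chance. The largest rises among genes of at least 10 CPM were those of Havcr1, which encodes the cell surface receptor TIM-1 (47.9-fold, from 0.462 ± 0.0319 to 22.4 ± 3.19 CPM), and Rsad2, an antiviral interferon-induced gene (40.1-fold, from 5.85 ± 1.77 to 236 ± 41.4 CPM). They were followed by Oas3, Stab1, Ccl9, Oas1g, Dnah10 and Cd40, with log2 fold changes between 4.51 and 3.87. Among the largest falls were those of Inmt, Kng2, Serpinb11, Hp, Imp3, Prss12 and Dach1, with log2 fold changes of -4.41, -4.28, -3.81, -3.57, -3.46, -3.26 and -3.16. In shCon 1, Hp stood at 87.3 CPM against 35.5 and 32.5 CPM in shCon 2 and 3, and Imp3 at 54.8 against 13.5 and 17.3 CPM. Without shCon 1, 8439 genes differed, and without shCopa 2 or shCopa 3, 3565 or 3533. In the lists that follow, members were named by the rule given with the processing. In some lists where 5 or fewer members moved against the rest, further ones were named after their values were seen. In other lists, such as the p53 targets and the checkpoint ligands, not all such members were named. Ranges of the numbers of list members that rose or fell, over fits that each left out 1 library, have their upper end in the fit without shCon 1 and their lower end in a fit without a shCopa library, in some lists shared with a fit without another shCon library.

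Interferon-stimulated genes rose throughout. All 36 tested members of the type I interferon list rose (36 of 36 also adjusted over the list alone), with a median log2 fold change of 2.01, and 33 to 36 rose with 1 library left out. Ifit1, whose product binds foreign RNA, rose 14.6-fold, from 10.4 ± 1.09 to 152 ± 25.7 CPM. Oas3 and Oas1g, which encode sensors of double-stranded RNA that make 2'-5'-linked oligoadenylate, rose 22.9-fold and 16.4-fold. Oas1g belongs to a family of near-identical copies, so its share of reads is uncertain. As a list the 36 genes shifted up relative to all other genes (camera, adjusted p = 7.58e-20; adjusted p = 0.219 with an estimated correlation). In the list of interferon-gamma and guanylate-binding protein genes, 19 of 25 rose, none fell and 6 did not pass; adjusted over the list alone, 19 rose and 1 fell. Gbp3 rose 5.57-fold, and Cd274, which encodes the checkpoint ligand PD-L1, rose 7.51-fold, from 4.36 ± 0.266 to 32.7 ± 5.43 CPM. This list had a median log2 fold change of 1.45 (camera, adjusted p = 1.02e-08; adjusted p = 0.219 with an estimated correlation), and without shCon 1 1 member fell. Ifnb1, the gene of interferon beta, had 0, 0 and 2 counts in shCon and 0, 2 and 1 counts in shCopa, too few to test at this depth.

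**Figure D2:**
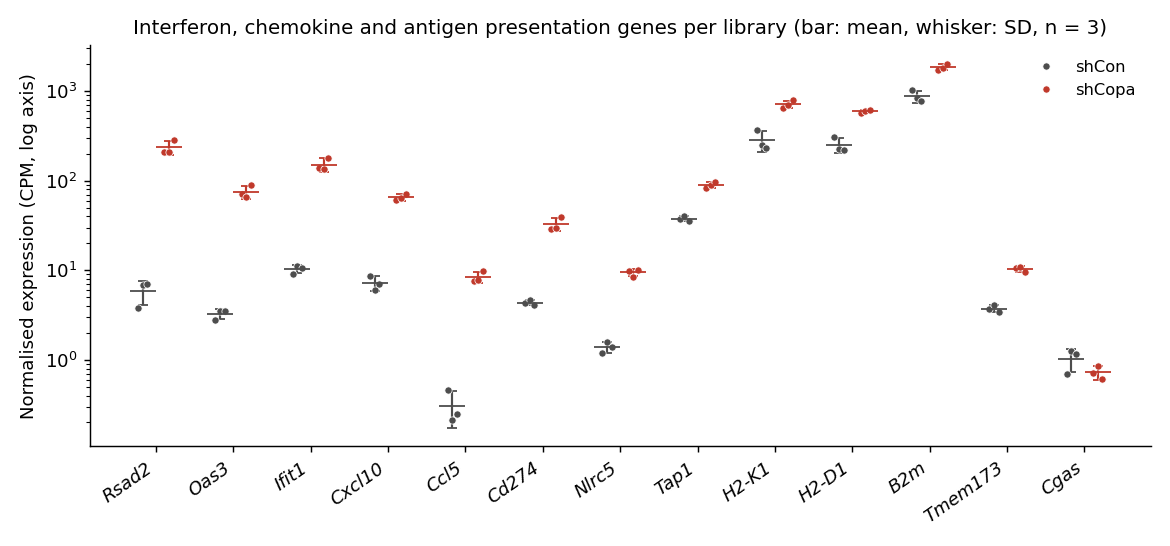
Normalised expression (vertical log axis, CPM) of 13 interferon, chemokine, sensing and antigen presentation genes in the 3 shCon libraries (grey points) and the 3 shCopa libraries (red points), with the mean as a bar and the SD as a whisker. In all but Cgas every shCopa library lies above every shCon library, as for Cxcl10, at 61.2 to 72.0 CPM against 6.01 to 8.73 CPM.

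In the list of nucleic acid sensing, which holds sensors, adaptors, kinases, nucleases and receptors, 12 of 22 members rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.61; camera, adjusted p = 0.00333; adjusted p = 0.219 with an estimated correlation). Tmem173 (Sting1), the adaptor of cytosolic DNA sensing, rose 2.78-fold, from 3.72 ± 0.337 to 10.3 ± 0.755 CPM. Ifi204, a DNA sensor, rose 8.35-fold, and Zbp1, a sensor of Z-form nucleic acid, 2.20-fold. Samhd1, which degrades deoxynucleotides, rose 2.12-fold. Cgas, the enzyme that makes the ligand of STING, was low in both groups, at 1.03 ± 0.293 and 0.727 ± 0.130 CPM, and did not pass (log2 fold change -0.50 ± 0.34, edgeR adjusted p = 0.286). The member that fell was Rnaseh2c, a subunit of ribonuclease H2 (-0.99 ± 0.21).

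For MHC class I antigen presentation, 11 of 25 genes rose, 3 fell and 11 did not pass; adjusted over the list alone, 13 rose and 4 fell. Nlrc5, the transactivator of class I genes, rose 6.73-fold, from 1.40 ± 0.191 to 9.46 ± 0.859 CPM. Tap1, a subunit of the peptide transporter, rose 2.41-fold, and B2m, the class I light chain, 2.12-fold. The heavy chain genes H2-K1 and H2-D1 rose 2.50-fold and 2.35-fold; they resemble one another and other H2 genes, so reads may be divided among them. The members that fell were Pdia3 (ERp57), a disulfide isomerase of the peptide-loading complex, to 26.0% of control (763 ± 34.6 to 198 ± 7.47 CPM), H2-T23 (-1.24 ± 0.21) and Tap2 (-0.45 ± 0.11). The list had a median of 0.38 (camera, adjusted p = 0.00765; adjusted p = 0.629 with an estimated correlation). H2-K1 stood at 373 CPM in shCon 1 against 252 and 233 CPM in shCon 2 and 3, and without shCon 1 the median was 0.65, with 17 members up and 5 down.

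Chemokine and cytokine transcripts rose in most members of their list. Of 29 tested, 20 rose, 4 fell and 5 did not pass; adjusted over the list alone, 20 rose and 5 fell. Cxcl10, a ligand of the T cell chemokine receptor CXCR3, rose 9.06-fold, from 7.24 ± 1.38 to 65.6 ± 5.66 CPM. Ccl5, a T cell attractant, rose 27.1-fold from 0.309 ± 0.136 to 8.41 ± 1.13 CPM. Cxcl1, a neutrophil attractant, rose 5.46-fold and Ccl9 19.0-fold. The members that fell were Cxcl12 (-3.01 ± 0.23), Il18 (-1.06 ± 0.16), Il33 (-0.86 ± 0.09) and Spp1 (-0.59 ± 0.14). Il6, named after its values were seen, had no count in any shCon library and 15, 14 and 11 counts in shCopa, at least 14-fold higher against a floor of 3 counts over the group. The list's median was 1.72, also with Il6 at its bound (camera, adjusted p = 6.43e-05; adjusted p = 0.219 with an estimated correlation). Among NF-kB targets, 15 of 22 rose, 1 fell (Sod2, -0.82 ± 0.13) and 6 did not pass, with the same counts adjusted over the list alone. Cd40, a co-stimulatory receptor, rose 14.7-fold, and the NF-kB inhibitors Tnfaip3 and Nfkbia rose 3.26-fold and 3.14-fold (median 0.65; camera, adjusted p = 8.64e-06; adjusted p = 0.219 with an estimated correlation). Of 17 checkpoint ligand and natural killer ligand genes, 8 rose, 4 fell and 5 did not pass, and adjusted over the list alone 8 rose and 5 fell (camera, adjusted p = 0.228). Besides Cd274, Raet1d, a ligand of the receptor NKG2D with close paralogs, rose 11.5-fold, while Ceacam1, an inhibitory ligand, fell to 38.4% of control. The count that fell ranged from 1 to 6 with 1 library left out.

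Transcripts of the secretory pathway moved in both directions. Hspa5, the ER chaperone BiP, rose 1.91-fold, while the disulfide isomerases Pdia3 and Pdia4 fell to 26.0% and 65.6% of control, and Calr, calreticulin, did not pass (log2 fold change 0.19 ± 0.09, edgeR adjusted p = 0.162). Of 25 ER chaperone and ER-associated degradation genes, 3 rose, 4 fell and 18 did not pass; adjusted over the list alone, 2 rose and 4 fell. Among 25 targets of the integrated stress response, 9 rose, 8 fell and 8 did not pass, and adjusted over the list alone 9 rose and 10 fell. Ddit3 (CHOP) rose 3.37-fold, Atf3, a stress-induced transcription factor, 4.11-fold and Ppp1r15a, which directs dephosphorylation of eIF2-alpha, 2.52-fold, while Stc2, a secreted glycoprotein, fell to 31.0% and Sesn2 to 47.9% of control. Of 24 COPI regulators and retrograde tethers, 4 rose, 3 fell and 17 did not pass, with the same counts adjusted over the list alone. Sec22b, an ER-Golgi SNARE, rose 1.61-fold, and Stx18, an ER SNARE for retrograde vesicles, and Arfgap1, which drives GTP hydrolysis on ARF1, fell to 50.1% and 62.0%. In the COPII list, 2 of 16 rose (Sec24d, 1.87-fold, and Sec23ip, 1.30-fold, the latter lost without any 1 shCopa library), none fell and 14 did not pass, as adjusted over the list alone. Of 16 CREB3-family Golgi stress genes, 5 rose, with Acbd3 at 1.71-fold, 3 fell and 8 did not pass, with the same counts adjusted over the list alone. No camera test passed for these lists or the COPI coat (adjusted p = 0.739 for ER chaperones, 0.766 for the integrated stress response, 0.992 for COPI regulators, 0.240 for COPII, 0.228 for Golgi stress and 0.917 for the COPI coat). The direction of COPI regulators was up beside a median of -0.01, and turned down with no low-count filter, the replicate block, offsets for transcript length and GC content, or without shCon 2, shCon 3 or shCopa 3. With fry, the COPI coat passed as down (adjusted p = 0.0404), and COPII (0.0339) and Golgi stress (0.00618) as up. The coat list holds Copa, the gene knocked down, so its fry result was partly set by the design. The coat was not tested without Copa. ER chaperones (fry, adjusted p = 0.0505), the integrated stress response (0.441) and COPI regulators (0.906) did not pass. Over fits that each left out 1 library, 2 to 7 ER chaperones rose and 3 to 9 fell, 4 to 10 integrated stress response genes fell, 4 to 8 COPI regulators rose and 2 to 6 fell, 1 to 9 COPII genes rose and 0 to 2 fell, 4 to 9 Golgi stress genes rose and 1 to 4 fell, and 1 to 4 coat subunits rose.

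Among 26 Golgi glycosylation enzymes, none rose, 10 fell and 16 did not pass, with the same counts adjusted over the list alone. St3gal4, a sialyltransferase, fell to 22.7% of control (144 ± 30 to 32.8 ± 0.480 CPM), Mgat3, which adds the bisecting N-acetylglucosamine, to 26.7% and the mannosidase Man2a2 to 40.2%. The median was -0.24 (camera, adjusted p = 0.0084; adjusted p = 0.219 with an estimated correlation), and 2 members rose without shCon 1, while with the length and GC offsets 4 rose and 14 fell. In the fatty acid and lipid droplet list, 10 of 22 fell, 1 rose (Scd1, 1.18 ± 0.18) and 11 did not pass; adjusted over the list alone, 11 fell and 2 rose. The lipid droplet coat genes Plin4 and Plin2 fell to 27.5% and 41.9% of control and Acsl1, an acyl-CoA synthetase, to 42.9% (median -0.31; camera, adjusted p = 0.00765; adjusted p = 0.219 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 rose, 5 fell and 14 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.917). Idi1, isopentenyl-diphosphate isomerase, rose 1.65-fold, while Mvd, mevalonate diphosphate decarboxylase, fell to 37.0%. From 3 to 9 of these rose and 2 to 7 fell with 1 library left out, and 1 to 3 of the fatty acid list rose.

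Glycolytic and hypoxia-regulated transcripts shifted down as a list. Of 27, 13 fell, 2 rose (Hk2, 0.96 ± 0.10, and Ndrg1, 0.34 ± 0.08) and 12 did not pass; adjusted over the list alone, 15 fell and 3 rose. Pdk1, which inhibits pyruvate dehydrogenase, fell to 32.8% of control, Slc16a3, a lactate exporter, to 27.3% and Egln3, a prolyl hydroxylase of hypoxia-inducible factor, to 24% (list median -0.37; camera, adjusted p = 0.00514; adjusted p = 0.629 with an estimated correlation). With 1 library left out, 8 to 17 fell and 1 to 3 rose, and with the length and GC offsets 13 fell and 5 rose. Of 25 nuclear-encoded oxidative phosphorylation genes, 11 fell, none rose and 14 did not pass, with the same counts adjusted over the list alone. Ndufv1, a complex I subunit, stood at 95.3, 65.1 and 63.3 CPM in shCon 1 to 3 and at 42.4 ± 0.339 CPM in shCopa (log2 fold change -0.81 ± 0.16). This list's median of -0.55 (camera, adjusted p = 0.00114; adjusted p = 0.737 with an estimated correlation) became -0.24 without shCon 1, and the number that fell was 16 without shCon 1, 2 without shCopa 1 or shCopa 2 and 1 without shCopa 3. Among 32 cytosolic ribosomal protein genes, 0 passed by edgeR, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, with Rpl27 at 267, 173 and 151 CPM in shCon 1 to 3 and 155 ± 11.6 CPM in shCopa. Their median of -0.14 (camera, adjusted p = 0.739) turned to 0.15 without shCon 1, where 15 rose and 1 fell (adjusted p = 0.0223), and to 0.06 with the length and GC offsets, where 7 rose and 1 fell. DESeq2 and limma-voom called 0 of them as well. Of 33 autophagy and lysosome genes, 4 rose, 9 fell and 20 did not pass, and adjusted over the list alone 4 rose and 10 fell (camera, adjusted p = 0.516). Sqstm1, the autophagy receptor p62, rose 2.42-fold, while Ulk1, the autophagy-initiating kinase, fell to 39.7% and Rragd, a GTPase of lysosomal mTORC1 signalling, to 42.0%; 2 to 12 rose with 1 library left out.

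Matrix transcripts rose more often than they fell. Of 30, 13 rose, 5 fell and 12 did not pass; adjusted over the list alone, 17 rose and 5 fell. Lamb3, a chain of laminin-332, rose 5.49-fold from 1.86 ± 0.173 to 10.2 ± 0.356 CPM and Ccn1, a matricellular protein, 3.15-fold from 196 ± 10.5 to 617 ± 33.2 CPM. The members that fell were Mmp14 (-1.14 ± 0.15), Mmp2 (-0.69 ± 0.11), Col6a1 (-0.55 ± 0.11), Col18a1 (-0.54 ± 0.09) and Col6a2 (-0.52 ± 0.13). The median was 0.41, or 0.25 without shCon 1 (camera, adjusted p = 0.0084; adjusted p = 0.675 with an estimated correlation), and 8 to 19 rose with 1 library left out. Of 19 epithelial-mesenchymal transition genes, 5 rose, 5 fell and 9 did not pass, with the same counts adjusted over the list alone, a median of -0.22 (-0.12 without shCon 1) and a mean of 0.08 (camera direction down, or up with the length and GC offsets, adjusted p = 0.834). The transcription factor Zeb2 rose 2.16-fold and the tight junction gene Ocln fell to 48.2%. Of 18 YAP and AKT pathway targets, 4 rose, 4 fell and 10 did not pass, and adjusted over the list alone 5 rose and 4 fell, with a median of -0.03 (-0.14 without shCon 1, 0.03 without shCon 2) and a mean of 0.14 (camera direction up, or down without shCon 1 or with no low-count filter, adjusted p = 0.917). F3, tissue factor, rose 2.24-fold and Lats2, a kinase that inhibits YAP, fell to 55.0%. With 1 library left out, 3 to 7 transition genes rose and 3 to 8 fell, and 4 to 7 pathway targets rose and 2 to 8 fell.

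Cell cycle lists showed few calls. Of 28 G2 and M phase genes, 4 rose, 1 fell and 23 did not pass, and adjusted over the list alone 2 rose and 1 fell (camera, adjusted p = 0.766). Tpx2, a spindle assembly factor, rose 1.62-fold and Ccnb1, cyclin B1, 1.35-fold, while Ccnb2, cyclin B2, fell to 70.9% of control. The median of 0.07 turned to -0.10 without shCon 1, where 5 members rose and 8 fell. Of 31 DNA replication and S phase genes, 3 rose, 1 fell and 27 did not pass, and adjusted over the list alone 1 rose and 0 fell (camera, adjusted p = 0.969). Orc1, of the origin recognition complex, rose 2.45-fold. Of 24 p53 targets, 10 rose, 4 fell and 10 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.228). The kinase gene Plk2 rose 4.37-fold and Pmaip1, the pro-apoptotic factor NOXA, 2.66-fold. Of 23 apoptosis and cell death genes, 5 rose, 5 fell and 13 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.925). Mlkl, the effector of necroptosis, rose 2.23-fold, while Bmf, a pro-apoptotic BH3-only gene, fell to 51.8% and Tnfrsf1a, a receptor of tumour necrosis factor, to 60.3%. With 1 library left out, 2 to 5 G2 and M genes rose and 0 to 8 fell, 1 to 7 S phase genes rose and 0 to 5 fell, and 2 to 8 cell death genes rose and 2 to 9 fell.

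Markers of bile duct cells shifted down as a list. Of 17 cholangiocyte markers, 7 fell, 2 rose (St14, 1.22 ± 0.18, and Cftr, 0.66 ± 0.16) and 8 did not pass, with the same counts adjusted over the list alone. Krt7, a duct keratin, fell from 680 ± 123 to 250 ± 18.7 CPM, Aqp1, a water channel, to 13.8% and Anxa4 to 57.0% of control (median -0.40; camera, adjusted p = 0.00984; adjusted p = 0.219 with an estimated correlation). The rise of 1 of the 2 was lost without shCopa 1 or shCopa 2. Of 8 hepatocyte markers tested, 3 rose, 3 fell and 2 did not pass, and adjusted over the list alone 4 rose and 3 fell; the median was 0.11 (0.43 without shCon 1, -0.08 without shCon 2) and the mean -1.34 (camera direction down, adjusted p = 0.992, but up with no low-count filter, the replicate block or the offsets, and without shCon 1, shCon 3 or shCopa 3). Alb, albumin, rose 2.29-fold to 22.7 ± 0.651 CPM. The fibrinogen chain gene Fgb fell to 14.2% and Fga to 4.13%. Fga had 26, 21 and 39 counts in shCon and 0, 2 and 1 in shCopa, near the floor, so its percentage is uncertain. Fgg, with 40, 16 and 19 counts in shCon and 0 in shCopa, was at least 24.2-fold lower. Of 4 leukocyte markers tested, 2 rose, 1 fell and 1 did not pass, as adjusted over the list alone: Ptprc (CD45) rose from 0.0280 ± 0.0243 to 1.09 ± 0.168 CPM and Lyz2 5.63-fold to 8.21 ± 0.225 CPM, while Csf1r fell to 53.2% of 165 ± 21.2 CPM. The 3 endothelial markers tested rose, as adjusted over the list alone, with Kdr at 1.86 ± 0.741, Eng at 4.14 ± 0.422 and Vwf at 0.904 ± 0.110 CPM in shCopa, and the call of Vwf was lost without shCon 3, shCopa 1 or shCopa 3, with DESeq2, with no low-count filter and with the replicate block. These 2 lists had too few members for a list test after the low-count filter. Without the filter the endothelial list (8 tested) shifted up (camera, adjusted p = 0.00171) and the leukocyte list did not pass (0.093). Camera without the filter was run with the preset correlation only, and the endothelial members it added had at most 14 counts in a library. Of 8 fibroblast and stellate cell markers, 3 rose (Acta2, Fap and Tagln, to 1.43 ± 0.304, 1.00 ± 0.0657 and 4.72 ± 1.08 CPM), 1 fell (Pdgfrb, -1.66 ± 0.36) and 4 did not pass; adjusted over the list alone, 5 rose and 3 fell (camera, adjusted p = 0.378; 0.0229 without the low-count filter), and 3 to 6 rose and 1 to 3 fell with 1 library left out.

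**Figure D3:**
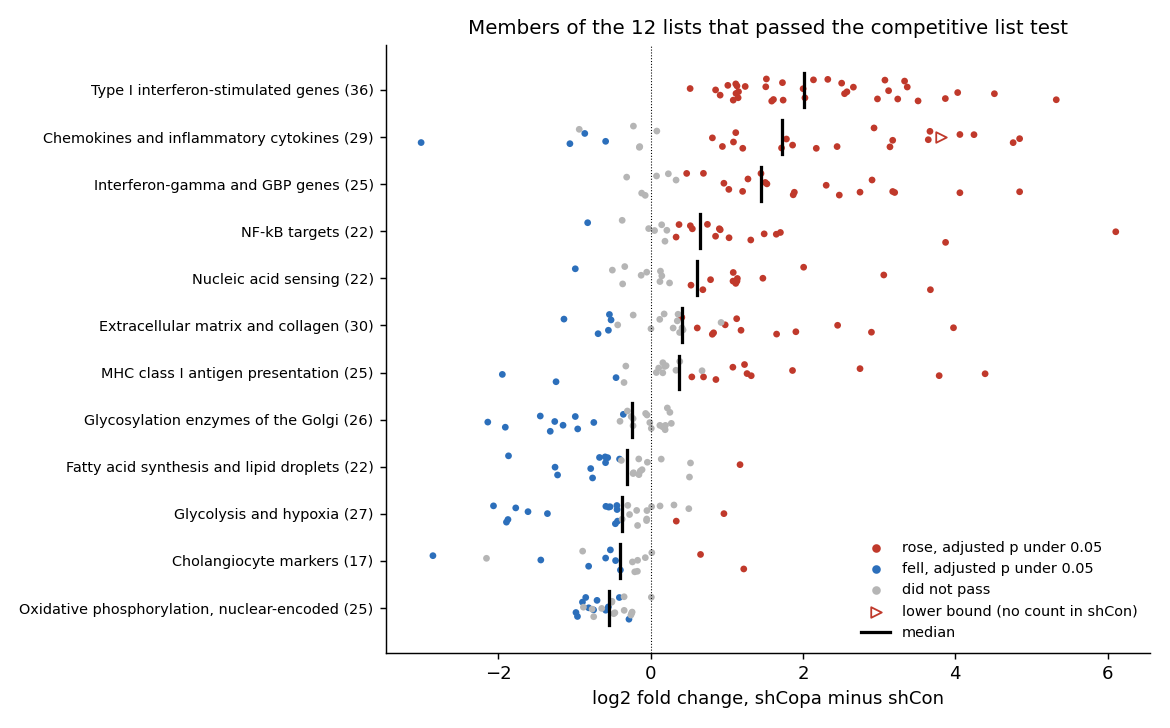
Log2 fold change (horizontal axis, shCopa minus shCon) of each tested member of the 12 lists that passed the competitive list test, with the number of members in brackets, members that rose in red, members that fell in blue, members that did not pass in grey and the median as a black bar. Il6, without a count in shCon, is drawn as an open triangle at its lower bound; the medians run from -0.55 for oxidative phosphorylation to 2.01 for type I interferon-stimulated genes.

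Of the 32 lists, 30 had enough members for camera, and 12 passed, 7 with a shift up and 5 with a shift down. With an estimated correlation between genes, 0 of the 12 kept their call (limma camera; 5 lists at an unadjusted p under 0.05), while fry, which tests whether the members of a list move on balance one way, passed 19 lists and missed oxidative phosphorylation (adjusted p = 0.109). Among lists that camera did not pass, fry passed 8. They were the COPI coat (which holds Copa itself), COPII, Golgi stress, checkpoint ligand, p53, epithelial-mesenchymal transition, fibroblast and YAP lists. With the preset correlation, splits of the 6 libraries that mixed the groups passed 5 to 9 lists. In such splits each side held unequal numbers of shCon and shCopa libraries, so part of the group difference stayed in the comparison. The lists they passed therefore do not give a rate of false calls.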

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

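The length and GC offsets were chosen after the data were seen; the other alternatives were set before. The counts of genes differing between shCopa and shCon, of genes higher in shCopa and of genes lower in shCopa stayed within 1.5 times with median-of-ratios and upper-quartile scaling (5400 and 5442 called), no low-count filter (5392), a filter of 1 CPM (5109), DESeq2 (5900), limma-voom (5386) and the offsets (7173), and no gene was called in opposite directions. At an absolute log2 fold change of at least 1, 2053 genes remained (1118 higher, 935 lower), and at an adjusted p under 0.01, 3177 (1590 higher, 1587 lower). Leaving out 1 library gave 3533 to 8439 genes (1778 to 4317 higher, 1755 to 4122 lower), with the most without shCon 1; 98.8% of the 5411 calls were kept there and 64.2% without shCopa 3. The number of lists that passed was 12 or 13 with 1 library left out, 14 with no low-count filter (endothelial and fibroblast markers added), 0 with an estimated correlation and 19 with fry. With 1 library left out, Copz1 ranged from -0.01 (without shCon 3) to 0.30 (without shCon 1) against 0.10 with all (0.13 with the offsets), and the ribosomal protein list from -0.27 (without shCon 3) to 0.15 (without shCon 1) against -0.14, or 0.06 with the offsets; beyond those offsets the cause was not tested. Replicate numbers did not pair the samples (correlations of same-number deviations -0.16, -0.06 and -0.11, and no library correlated best with its own number); with the replicate block, 3903 genes were called and the calls of Arcn1, Vwf (also lost with DESeq2 and with no low-count filter), Mcm10 and Slbp were lost, and 4 oxidative phosphorylation genes fell. Copa passed in every fit of single genes listed here. Of changes of 1.5-fold, simulation recovered 20.9%. Far fewer genes were changed there, with 149 calls against 5411 here, so an adjusted p under 0.05 asked for a smaller p. The 20.9% is therefore not the share found in these data, though changes of that size can still be missed.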

Other observations

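Tests of shCon 1, of leukocyte RNA and of the gene families were chosen after the results were seen. So was that of sites upstream in the genes not used to pick a hexamer. The hexamer scan and the thinning of libraries were not among the tests fixed before the data were examined. The hexamer was picked from the same data it was tested on. Transcripts of complement, coagulation and the acute phase fell in most members of a group drawn up after the values were seen: of 15 tested, 10 fell and 3 rose. C4b fell from 19.7 ± 2.01 to 2.22 ± 0.451 CPM, Kng1 from 1.88 ± 0.563 to 0.142 ± 0.105 CPM and the abundant C3 from 1560 ± 152 to 1090 ± 23.4 CPM. The members that rose were C1s1 (log2 fold change 0.52 ± 0.14), C1ra (0.80 ± 0.12) and Cfb, the last from 1.23 ± 0.264 to 2.85 ± 0.355 CPM. Among small proline-rich protein genes of the cornified envelope, 3 of 4 fell, Sprr1a from 177 ± 20.7 to 24.7 ± 1.83 CPM and Sprr2g from 93.3 ± 3.16 to 12.1 ± 1.14 CPM. All 6 tested genes and pseudogenes of the Zscan4 family, known from a transient state of mouse embryonic stem cells, fell, Zscan4f from 1.92 ± 0.880 to 0.135 ± 0.152 CPM. These copies share reads, so the 6 are not independent.

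More genes had a count in shCopa. After thinning every library to 19634876 counts, 21236 to 21818 genes had at least 1 count in the shCopa libraries and 19718 to 20229 in the shCon libraries.

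shCon 1 stood apart from shCon 2 and 3. A swap with a shCopa library is argued against by Copa, at 2.27 times the shCopa mean in shCon 1. The shCopa libraries were at 182 to 187 CPM. Any other sample with Copa at the control level would look the same here, so other wrong labels stay open. A trend on transcript length may be part of the difference: across genes, which are not independent replicates, its deviation from the rest of its group correlated with length at rho = -0.54, against -0.09 to 0.13 in the shCopa libraries and 0.46 and 0.45 in shCon 2 and 3, whose deviations are taken partly from shCon 1. Length and GC trends were not the whole of it, since the SD of its deviation was 0.55 (log2) after they were removed, above the 0.40 of the next library. What remains, such as a different culture or library preparation, was not tested.

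All 36 type I interferon-stimulated genes tested were higher in shCopa. Leukocyte RNA is argued against as their source by 5 abundant leukocyte transcripts, picked from the list of leukocyte markers after the results were seen. Tyrobp, Fcer1g, Laptm5, Coro1a and Cd52 summed to 0.272 CPM in shCopa and 0.131 CPM in shCon. The interferon genes rose by 2784 CPM in sum. Single markers of other cells did rise, Ptprc from 0, 1 and 1 counts to 21, 25 and 25, Lyz2 from 39, 33 and 28 to 185, 185 and 167, and the endothelial Kdr, Eng and Vwf to at most 4.14 CPM on average, and why they rose was not tested. The length trend of shCon 1 is also argued against, as 36 of 36 rose with the offsets and 36 of 36 without that library. The rise may belong to the knockdown cells themselves, as a hypothesis, and with 1 knockdown group in the labels, whether it follows from the loss of Copa or from the knockdown reagent or its vector was not tested.

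Genes with the hexamer GGACCT in the 3' UTR were lower in shCopa (coefficient -0.11 ± 0.014 SE on the log2 scale, z = -7.59). That z was the lowest of 4096 hexamers and below the -4.22 that 95% of 1000 shuffles stayed above. GGACCG (-0.135 ± 0.022, z = -6.03) and GACCGA (-0.123 ± 0.024, z = -5.23), which share GACC with it, had lower coefficients. AATGCC, without GACC, had z = -6.67. The SE, z and shuffles treat genes as independent, which they are not, and leave out the spread between libraries. The length trend of shCon 1 is argued against as the cause, with z = -7.52 for GGACCT without that library. With the offsets z was -7.60, but the scan already removed trends on length and GC content, so the offsets could hardly change it. Pairing of a small RNA with 3' UTR sites stays open: in the genes not used to pick it, the overlapping hexamer AGGACC had z = -4.49, but the coefficient was -0.093 ± 0.021 for 3' UTR sites and -0.064 ± 0.019 for sites upstream, and their difference of -0.030 ± 0.028 does not tell a larger fall from an equal one. For GGACCT over all genes the difference was -0.064 ± 0.020, with -0.046 ± 0.013 for sites upstream, but that hexamer was picked for its fall with 3' UTR sites, which tilts the difference. Genes with 2 or more sites (-0.058 ± 0.020) were no lower than genes with 1 (-0.060 ± 0.013), the pick from the other set of genes was AATGCC (z = -3.02 in the first, with -0.063 for 3' UTR sites and -0.048 for sites upstream, a difference of -0.015 ± 0.029), and whether a small RNA would be a strand of the knockdown reagent or one of the cell was not tested.

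Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. In all but the real split, each side held unequal numbers of shCon and shCopa libraries. Part of the group difference then stayed between the sides and the rest widened the spread within them, so their calls do not measure chance alone. The real split called 5411 genes and 12 lists, and the highest of the others 0 genes (edgeR; 37 to 622 at an unadjusted p under 0.05) and 9 lists; 1 split, the real one, reached each of these numbers.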
